A study of Homo sapiens with 12 samples.

How the data were processed

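Transcript levels were measured on 12 Illumina HumanWG-6 v3 bead arrays, which carry 1 colour and hold 48803 probes for human transcripts. Per the labels, 4 arrays held undifferentiated SNUhES3 cells, an established human embryonic stem cell (ESC) line, 4 held embryoid bodies (EBs) cultured for 1 week and 4 held EBs cultured for 2 weeks. Per the labels' protocols, the ESCs grew on mouse STO feeder cells that could no longer divide, with basic FGF in the medium, and the EBs floated in the same medium without that factor. Total RNA was taken up with a column kit, checked for quality on a Bioanalyser and labelled with Cy3. Nothing in the labels says whether the 4 arrays of a group came from separate cultures, so the p-values measure the spread between these arrays, which can be technical.

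The deposited table without normalization held an intensity per probe and array on a linear scale, with 1 detection p-value per probe and array, per the file headers. The detection p-values moved in steps of 1 in 759, which is the rank of a probe among negative control probes, and the scanner software and its background handling were not given in the sources used here. A second deposited table, the series matrix, held log2 values with the same quartiles in every column, as after quantile normalization, and no centring of genes. Its median was 6.68 in each of the 12 columns, and 1 or 2 probes per column had no value. Its direction was settled by its correlation with the log2 signal of the same array, which was above 0.997 on 11 arrays and 0.938 on the second 2-week array. How the authors made it was not given in the sources used here. That table was used as an alternative only. All per-sample columns of both tables were used.

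Signals were corrected and normalized with the neqc function of limma 3.58.1 in R 4.3.3, which estimates the background from the detection p-values, adds an offset of 16, normalizes between arrays by quantiles and takes log2. Quantile normalization gives all arrays the same distribution and so removes any change that moves most transcripts one way. Because normal background correction with an offset shrinks differences of dim probes, differences near background are underestimated. Probes with a detection p-value under 0.01 on at least 4 of the 12 arrays were kept, which left 15921 probes. Gene names came from the platform annotation supplied with the tables: 27578 probes had 1 symbol, 13 had several and 21212 are unnamed here. Of the named probes, 27541 were matched by Entrez ID to the gene table of assembly GRCh38.p14, which updated 0 symbols, and no coordinates were used. Among the kept probes 13586 had 1 symbol, and the probe with the highest mean over the 12 arrays stood for its gene, which gave 10562 genes. Where other probes of a named gene went the other way, this is said beside the gene. Folds are those of the chosen probe, and other probes of a gene can give smaller ones.

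Each group comparison was fitted with limma's lmFit and eBayes on all 12 arrays, so that the 3 groups shared 1 estimate of the spread (prior degrees of freedom 4.31), with a two-sided moderated test and Benjamini-Hochberg adjustment over all genes of a comparison. A gene was called at an adjusted p under 0.05 and an absolute log2 difference of at least 1, which is a 2-fold minimum. In the text, rose, fell, higher and lower refer to genes called in this way unless a value is given alone. A probe not detected on any array of a group has only a bound there. For such genes the fold is given as at least N-fold, from the mean of the group that measured it and the mean, over the arrays of the other group, of the higher of the probe's own value and the lowest normalized value among detected probes of that array. That floor lay between 6.67 and 7.28 on the log2 scale. No fold is given where both groups were below background. List medians with bounds put a member undetected in 1 group at its bound. They leave out members below background in both groups and members whose bound did not exceed 1-fold. They can therefore exceed the plain median.

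Before the data were examined, 28 gene lists were fixed, 12 of them as core lists of pluripotency, germ layers, cell types and FGF signalling. Lists with at least 5 tested genes, 27 of the 28, were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with a correlation estimated per list and with limma's fry. Only members kept by the detection filter were tested or counted. Tested were 10 of 15 mesendoderm, 13 of 29 HOX, 8 of 22 trophoblast and 13 of 27 cardiomyocyte genes named on the array. A member undetected in ESCs was kept only through EB arrays, so its higher level in EBs was largely fixed by the filter. The rule for named genes was fixed at the same time as the lists. It took POU5F1, NANOG and SOX2, the 4 largest rises and 4 largest falls among called genes whose groups did not overlap, the 2 called members with the largest difference from each core list (or the 1 with the largest difference, as a value, where no member was called), and the called member with the largest difference from each other list. Symbols beginning with LOC, HS., FLJ, KIAA or MGC, symbols of the form C1orf2, and sex-linked marker genes were left out. For genes called in both time steps it took the 3 per direction whose smaller difference was largest. Other genes were named only after their values were seen, which is said where it applies.

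Whether replicate numbers pair arrays across groups was checked on the data. Same-numbered arrays of 1-week EBs and ESCs deviated together from their group means, with correlations across genes of 0.138 to 0.245, which counts as pairing by the rule used here, although nothing in the labels states it. Across these 2 groups, differently numbered arrays within numbers 1 and 2 or within numbers 3 and 4 deviated together about as much (0.121 to 0.251), so the correlation followed these array pairs and does not single out the replicate number. The fit without the block was kept, and the blocked fit was an alternative. The column names did not identify the chip, so a chip block was not run.

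The steps were tested on simulated data. For the comparison of 1-week EBs with ESCs, 10562 genes were drawn from the real means and spreads with 67, 67 and 66 genes changed by log2 1.5, 2 and 3, of which 100% were recovered at each size, with 0 false calls, or 6 without the fold minimum. With 80% of the residual variance shared within array pairs, 100% were again recovered, with 2 false calls, or 550 without the fold minimum. In a simulation of 20000 probes, the neqc step returned a true log2 difference of 2 as 1.88. In a simulation of 10562 genes drawn independently of each other, camera called 0% of 200 unchanged lists, which does not test lists of correlated genes.

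Alternatives fixed before the data were examined were no background correction, normexp with an offset of 50, scaling to equal medians, the series matrix, no detection filter, detection on all 12 arrays, a detection p under 0.05, the mean of all probes of a gene, the most variable probe, a trended robust variance, array quality weights, only the 2 groups compared, the replicate number as a block, no fold minimum, limma's treat against a log2 difference of 1, and leaving out each array in turn. Chosen after the data were seen were the means of arrays 1 and 2 and of arrays 3 and 4 as samples, those pairs as a random block, each pair of arrays alone, and the series matrix without the second 2-week array. Comparisons that share a group share its chance deviations, so overlaps of calls were set beside 100 simulations of unchanged groups, beside the overlap of independent lists, and beside fits with the shared group split. In these simulations no gene changed, so hardly any gene was called and overlaps of 0 were fixed in advance. They do not measure overlap among genes that do change. Sex-linked marker genes were not analysed here.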

Results

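Gene expression was profiled in SNUhES3, a human embryonic stem cell (ESC) line, and in embryoid bodies (EBs) made from it, floating aggregates in which ESCs differentiate into many cell types at once. The 3 groups, with 4 arrays each, were undifferentiated ESCs, EBs after 1 week and EBs after 2 weeks of culture without basic FGF, the growth factor that had been present in the ESC medium. Mean probe intensity was 902 ± 86.9 (SD, n = 4) in ESCs, 991 ± 78.0 in 1-week EBs and 879 ± 122 in 2-week EBs, with the lowest single mean, 718, on the second 2-week array. Between 14045 and 15905 of the 48803 probes were detected per array, and 10562 named genes were tested. The number of arrays limits the precision of every value. Across these genes, which are not independent replicates, ESC arrays correlated with 1-week arrays at 0.918 to 0.934 and with 2-week arrays at 0.887 to 0.901, while 1-week and 2-week arrays correlated at 0.978 to 0.984.

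Arrays within a group were not equally similar. In ESCs and 1-week EBs, arrays 1 and 2 resembled each other, and so did arrays 3 and 4, with correlations of at least 0.997, against 0.987 in ESCs and 0.992 in 1-week EBs for the other array combinations. In 2-week EBs, arrays 3 and 4 were again above 0.997, whereas arrays 1 and 2 correlated at 0.992, within the 0.990 to 0.995 of the other combinations. Where the mean levels of a tested list did not overlap between the pairs of a group and differed by more than log2 0.2, the values are given beside that list.

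Transcripts of POU5F1, NANOG and SOX2, transcription factors at the core of the pluripotency network, were measured on every array of every group. POU5F1 was at log2 14.11 ± 0.06 (SD, n = 4) in ESCs, 13.94 ± 0.32 in 1-week EBs and 13.44 ± 0.04 in 2-week EBs. Its 1-week arrays stood apart in pairs, at 14.19 and 14.23 on arrays 1 and 2 and at 13.64 and 13.70 on arrays 3 and 4. The difference from ESCs was -0.18 (SE 0.12, adjusted p = 0.243) at 1 week, or 0.05 from arrays 1 and 2 alone, and -0.67 (adjusted p = 0.000271) at 2 weeks. NANOG differed from ESCs by -0.10 (adjusted p = 0.423) and -0.82 (adjusted p = 5.42e-06), and SOX2 by -0.15 (adjusted p = 0.165) and 0.00 (adjusted p = 0.988). At 2 weeks the POU5F1 and NANOG differences passed the adjusted p and stayed under the 2-fold minimum. The 1-week NANOG difference was 0.04 with median scaling, and the 2-week SOX2 difference was 0.07 from its other probe, so neither sign was settled.

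The comparison of 1-week EBs with ESCs asked which transcripts change when aggregated cells leave the undifferentiated state. After 1 week, transcripts of connective tissue, heart, endoderm and liver or yolk sac were abundant in EBs, and many of them lay below background in ESCs. COL3A1, a fibrillar collagen chain, rose at least 115-fold, from 5.13 ± 0.18 to 13.93 ± 0.31 on the log2 scale (SD, n = 4, adjusted p = 8.04e-15). LUM and DCN, proteoglycans that bind collagen fibrils, rose at least 89.9-fold and 45.2-fold by their brightest probes. Their other probes gave smaller log2 differences, 5.89 for LUM and 1.41 to 4.19 for DCN. HAND1, a transcription factor of heart and extraembryonic mesoderm, was measured in both groups and rose 118-fold, from 7.91 ± 0.11 to 14.80 ± 0.11. The fixed rule picked genes by fitted difference, which sets no order among genes that have only a bound. It named the falls of NPTX1, a secreted neuronal pentraxin, by 16.7-fold (log2 -4.06, SE 0.10), GARIN1B, at least 5.41-fold, CH25H, the cholesterol 25-hydroxylase, at least 4.11-fold, and SNORD35A, a small nucleolar RNA, at least 3.71-fold.

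Germ layer lists rose together at 1 week, though members undetected in ESCs were kept only through EB arrays. Of 18 measured genes for secreted proteins of liver and yolk sac, 15 were higher and 3 did not pass (camera adjusted p = 1.24e-15). Their median was log2 4.03, or 3.04 with undetected members at their bound where that bound exceeded 1-fold. FGB, the fibrinogen beta chain, was at least 35.3-fold and TTR, the thyroxine carrier transthyretin, at least 23.6-fold higher. In the mesenchyme and extracellular matrix list 18 of 23 members were higher and 5 did not pass (median 2.45, or 2.07 with bounds, adjusted p = 1.24e-15), led by COL3A1 and LUM. The 1-week means of that list were 11.62 and 11.67 on arrays 1 and 2 and 11.34 and 11.33 on arrays 3 and 4. Primitive streak and mesendoderm genes were higher in 9 of 10 cases (median 2.00, or 1.28 with bounds, adjusted p = 5.15e-08). EOMES, a T-box factor of mesendoderm, rose at least 5.85-fold and CER1, a secreted inhibitor of NODAL and BMP, at least 3.38-fold. Endoderm genes were higher in 9 of 11 cases (median 2.43, or 1.33 with bounds, adjusted p = 6.99e-07). FOXA2, a pioneer factor of endoderm, and CDX2, a hindgut and trophectoderm factor, exceeded ESCs at least 8.32-fold and 3.29-fold. For cardiomyocytes, 9 of 13 members were higher, 1 was lower and 3 did not pass (median 2.46, or 1.41 with bounds, adjusted p = 4.59e-06). SLN, sarcolipin, which inhibits the calcium pump of the sarcoplasmic reticulum, rose at least 36.4-fold beside HAND1, whereas TNNI3, cardiac troponin I, named after its value was seen, fell (log2 -1.68). The HOX list had 8 of 13 members higher (median 2.39, or 0.50 with bounds, adjusted p = 1.03e-05). HOXB8 and HOXB5, which pattern the trunk, were at least 9.76-fold and 9.61-fold higher. These 6 calls held with an estimated correlation (adjusted p = 0.00395, 0.0497, 0.0452, 0.0317, 0.0452 and 0.0452 in this order). The call of the imprinted genes, of which 5 of 13 were higher, held too (median 0.55, adjusted p = 0.00582, and adjusted p = 0.0452 with an estimated correlation). IGF2, a fetal growth factor, was at least 7.63-fold higher.

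Neural lists had medians of 0.58 and -0.03 at 1 week. Neural progenitor genes were higher in 8 of 18 cases and did not pass in 10 (median 0.58, or 0.35 with bounds, adjusted p = 0.00213, but adjusted p = 0.255 with an estimated correlation). NR2F1, an orphan nuclear receptor of the developing brain, and POU3F2, a neural POU factor, were at least 6.48-fold and 4.18-fold higher. The 1-week arrays stood apart in this list, with mean log2 levels of 8.95 and 8.94 on arrays 1 and 2 and 9.31 on each of arrays 3 and 4. In the neuron list 5 of 23 members were higher, 1 was lower and 17 did not pass, and the list did not pass (median -0.03, mean 0.21, test upward, adjusted p = 0.824), its median being 0.17 with median scaling. STMN2, a regulator of microtubules in neurites, rose 3.42-fold and NCAM1, a neural cell adhesion molecule detected on 3 of 4 ESC arrays, 2.67-fold, or log2 0.99 in the series matrix. GAP43, a growth cone protein named after its value was seen, fell (log2 -1.40). The higher members include SNAP25 (log2 1.33), likewise named after its value was seen, whose other probe lay at -0.19. Mean levels of that list were 8.43 and 8.42 on arrays 1 and 2 and 8.76 and 8.71 on arrays 3 and 4, against 8.35 to 8.38 in ESCs.

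Pluripotency genes were mixed at 1 week: 3 of 26 were higher, 4 were lower and 19 did not pass (median -0.16, adjusted p = 0.0329, but adjusted p = 0.0773 with an estimated correlation). DPPA2, a chromatin-associated pluripotency gene, fell by 1.56 on the log2 scale, as did FOXD3, PRDM14 and UTF1, which are transcriptional regulators of pluripotent cells, by 1.07, 1.03 and 1.04. The 3 members that rose belong to the NODAL branch of TGF-beta signalling: NODAL itself, at least 3.74-fold, its inhibitor LEFTY1 (log2 1.01) and the ligand GDF3 (log2 1.11). Except for DPPA2 and NODAL, these members were named after their values were seen. In the list of FGF and ERK feedback genes 2 of 16 were higher, 3 were lower and 11 did not pass (median 0.04, mean -0.09, test downward, adjusted p = 0.678). EGR1, an immediate early transcription factor, fell 3.37-fold, and DUSP6, a phosphatase that limits ERK, rose 2.5-fold. Immediate early and unfolded protein response genes were lower in 7 of 20 cases and higher in 1 (median -0.41, adjusted p = 0.00914, but adjusted p = 0.183 with an estimated correlation). FOSB, an AP-1 subunit, fell 5.86-fold, and the member that rose was ASNS, asparagine synthetase (log2 1.02, or 0.59 by its other probe), named after its value was seen.

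Further lists passed camera at 1 week only with the preset correlation. Trophoblast genes were higher in 4 of 8 cases (median 1.13, or 0.31 with bounds, adjusted p = 0.00322, but adjusted p = 0.0722 with an estimated correlation). SLC40A1, the iron exporter ferroportin, was at least 12.1-fold higher and TFAP2A, a factor of trophoblast, neural crest and ectoderm, 4.63-fold, with other TFAP2A probes at -0.66 to 2.43. For WNT targets 6 of 10 were higher (median 1.90, or 0.95 with bounds, adjusted p = 0.00235, but adjusted p = 0.183 with an estimated correlation). LEF1, a nuclear effector of WNT signalling, rose 8.80-fold. BMP targets were higher in 5 of 12 cases (median 0.62, or 0.30 with bounds, adjusted p = 0.0329, but adjusted p = 0.083 with an estimated correlation, and 0.0602 to 0.106 without any 1 of the 1-week arrays, where the median was 0.37 to 0.41). MSX1, a homeobox target of BMP, rose 20.6-fold. Neural crest genes, which include MSX1, were higher in 4 of 11 cases and lower in 1, the pluripotency gene FOXD3 (median 0.90, or 0.48 with bounds, adjusted p = 0.0329, but adjusted p = 0.136 with an estimated correlation, and 0.0551 to 0.0702 without any 1 of the 2-week arrays). Endothelial genes were higher in 5 of 11 cases (median 0.57, or 0.21 with bounds, adjusted p = 0.0388, but adjusted p = 0.132 with an estimated correlation, 0.0926 in the series matrix, and 0.105 to 0.126 without any 1 of the 2-week arrays). CDH5, the endothelial cadherin, was at least 1.17-fold higher and TEK, the angiopoietin receptor, 3.09-fold.

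The remaining lists did not pass camera at 1 week, though single members did, and p-values of lists here are from camera. By fry, erythroid (adjusted p = 0.00507), smooth muscle (0.00923) and mitosis genes (0.00128) passed upward. Simple epithelium (0.00197) and hypoxia genes (0.000503) passed downward by fry. Erythroid genes were higher in 3 of 7 cases (median 0.73, adjusted p = 0.66). HBG2, a fetal globin chain, rose at least 5.10-fold, to 8.66 and 8.66 on arrays 1 and 2 and to 10.15 and 10.28 on arrays 3 and 4. The list mean followed the same pairs at 7.83, 7.86, 8.72 and 8.69. Of 5 leukocyte genes LCP1, an actin bundling protein of blood cells, rose at least 6.25-fold and CORO1A, an actin regulator of the same cells named after its value was seen, fell (log2 -1.13). Leukocyte means were 8.46, 8.50, 8.68 and 8.70 on ESC arrays 1 to 4 and 8.44, 8.53, 8.70 and 8.67 at 1 week. That list had a median of -0.70, a mean of 0.00 and a downward test (adjusted p = 0.212). Among 8 smooth muscle genes ACTA2, smooth muscle actin, rose 5.28-fold (list median -0.12, mean 0.27, test upward, adjusted p = 0.982). Surface ectoderm, with 4 measured genes, was counted without a test, and DSC3, a desmosomal cadherin, was at least 3.54-fold higher. Simple epithelium had 2 of 14 members higher and 1 lower (median -0.39, adjusted p = 0.166). KRT18, an epithelial keratin, rose 2.40-fold by its brightest probe, with its other probes at -0.47 to 0.15 and the mean of its probes at 0.32, so that call rested on the choice of probe. In the hypoxia and glycolysis list 2 of 23 were higher and 1 was lower (median -0.14, adjusted p = 0.23), and NDRG1, a gene induced by hypoxia and differentiation and detected on 3 of 4 ESC arrays, rose 2.97-fold, or by log2 1.34 without passing in the series matrix (adjusted p = 0.0546, though it was called there without 2-week array 2). Mitosis (median 0.07, adjusted p = 0.66), DNA replication (median -0.05, mean 0.04, test downward, adjusted p = 0.832), cytosolic ribosomal proteins (median 0.01, or -0.18 with median scaling, adjusted p = 1), cholesterol synthesis (median -0.12, adjusted p = 0.46) and p53 targets (median -0.11, adjusted p = 0.678) did not pass.

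In all, 643 genes were higher and 324 lower in 1-week EBs, 9.16% of those tested, and 66.5% of the called genes were higher. The arrays of the 2 groups did not overlap for 964 of these 967 genes and for 48.5% of all tested genes. Chance gives 2.86% if all arrays are exchangeable, and a larger share if the array pairs are the units. Of the called genes 367 higher and 75 lower have only a bound in the dimmer group, and 5 were below background in both. Adjusted over the list alone, the counts of higher and lower members were the same in all 28 lists. With arrays scaled to equal medians, 795 were higher and 223 lower, so that 78.1% were higher, and the median of all genes was 0.13 in place of 0.01.

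**Figure D1:**
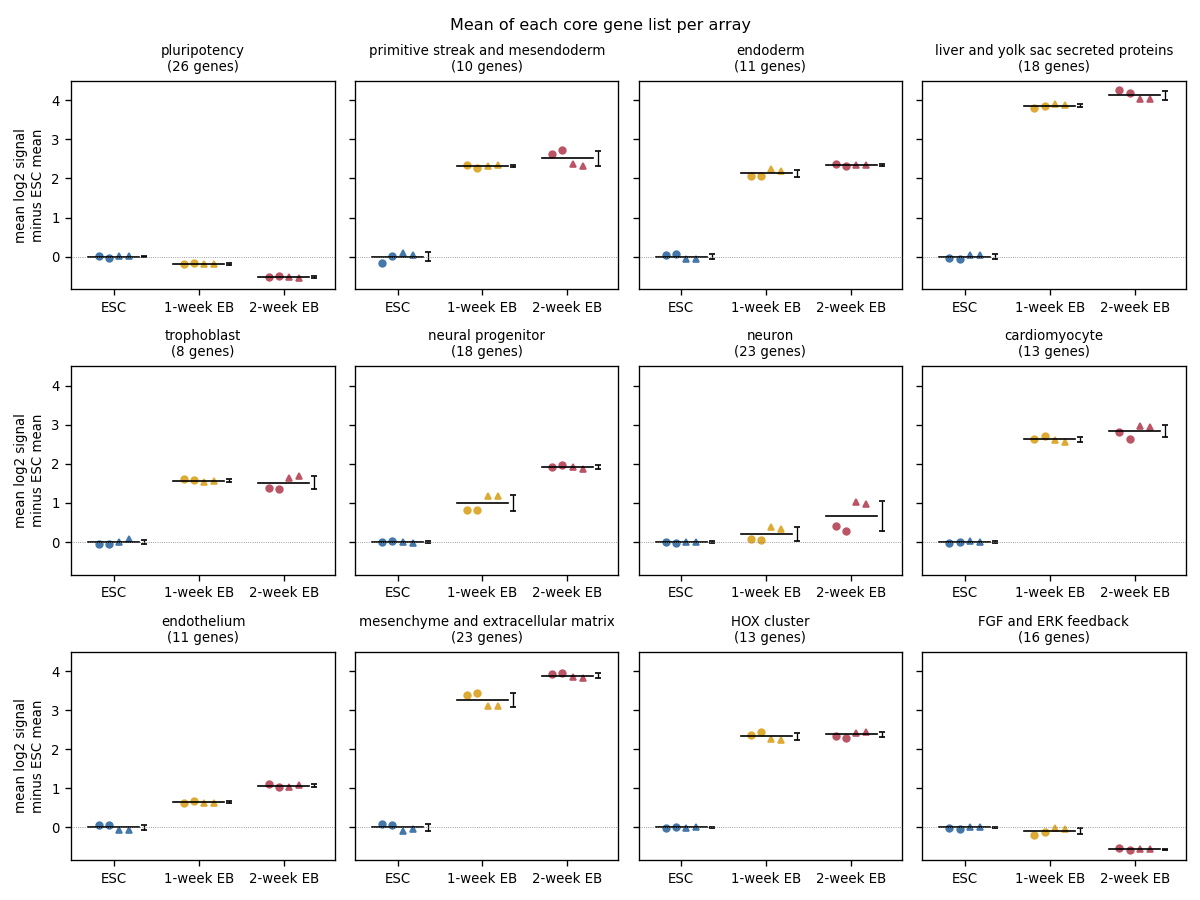
Mean log2 level of each of the 12 core lists on each array, minus the mean of the ESC arrays (vertical axis, log2 units), for the 3 groups on the horizontal axis. Circles are arrays 1 and 2, triangles arrays 3 and 4, black lines group means and bars the SD of 4 arrays. Both pairs of 2-week arrays stand apart in the neuron list, and the sign of the neuron median at 1 week turned with median scaling and in the series matrix, and that of the trophoblast median between both weeks in the series matrix.

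The comparison of 2-week EBs with ESCs asked how far the cells had moved after 2 weeks. By the same rule COL3A1, LUM, DCN and PITX1 were named among the rises, each with only a bound. COL3A1 rose at least 235-fold, to 14.97 ± 0.16 (SD, n = 4, adjusted p = 1.83e-15), LUM at least 132-fold, DCN at least 127-fold and PITX1, a homeobox factor of hindlimb and oral ectoderm, at least 59.8-fold. Other probes gave smaller log2 differences, 6.79 for LUM and 2.74 to 5.53 for DCN. HAND1 stood 126-fold above ESCs (log2 6.98, SE 0.07). The falls named were NPTX1, 18.7-fold and detected on 2 of 4 arrays, EGR1, 17.9-fold (log2 -4.16, SE 0.06), FOS, an AP-1 subunit, 15.9-fold, and CH25H, at least 3.80-fold.

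Of the germ layer lists, liver and yolk sac proteins were higher in 15 of 18 cases (median 4.32, or 3.16 with bounds, adjusted p = 5.04e-13), FGB at least 48.5-fold and TTR at least 25-fold. Endoderm genes were higher in 9 of 11 cases (median 2.83, or 1.69 with bounds, adjusted p = 8.30e-06), with FOXA2 at least 9.65-fold and CDX2 at least 3.47-fold above ESCs. In the cardiomyocyte list 9 of 13 were higher, 1 was lower, again TNNI3 (log2 -1.62), and 3 did not pass (median 3.45, or 1.92 with bounds, adjusted p = 1.12e-05), and SLN exceeded ESCs at least 52.0-fold. Cardiomyocyte means at 2 weeks were 9.84 and 9.68 on arrays 1 and 2, on average log2 0.23 below those of arrays 3 and 4. Imprinted genes were higher in 6 of 13 cases (median 0.67, adjusted p = 0.00101), with IGF2 at least 11.8-fold higher. These 4 calls held with an estimated correlation (adjusted p = 0.0299, 0.0299, 0.0436 and 0.00808 for imprinted, endoderm, cardiomyocyte and liver genes). Mesenchyme and matrix genes were higher in 20 of 23 cases (median 3.25, or 2.58 with bounds, adjusted p = 1.02e-13, but adjusted p = 0.0584 with an estimated correlation). All 10 tested mesendoderm genes were higher (median 2.25, or 1.15 with bounds, adjusted p = 3.94e-07, but adjusted p = 0.0552 with an estimated correlation). Undetected in ESCs were 9 of these and all 8 HOX genes called higher, so their direction was largely fixed by the detection filter. EOMES rose at least 6.29-fold and MIXL1, a homeobox factor of the primitive streak, at least 3-fold. Mesendoderm means were 8.51 and 8.60 on arrays 1 and 2 and 8.24 and 8.20 on arrays 3 and 4. HOX genes were higher in 8 of 13 cases (median 2.69, or 0.72 with bounds, adjusted p = 0.000252, but adjusted p = 0.0584 with an estimated correlation), HOXB8 at least 12.1-fold and HOXB5 at least 11.2-fold.

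Neural lists had medians of 1.84 and 0.45 at 2 weeks. Neural progenitor genes were higher in 11 of 18 cases (median 1.84, or 1.01 with bounds, adjusted p = 6.66e-07, but adjusted p = 0.0823 with an estimated correlation). LHX2, a LIM homeobox factor of forebrain and eye field, rose 19.1-fold, from 7.26 ± 0.14 to 11.51 ± 0.26, and NR2F1 at least 6.61-fold. The neuron list had 11 of 23 members higher, 1 lower and 11 that did not pass. As a list it did not pass camera (median 0.45, adjusted p = 0.172) but passed upward by fry (adjusted p = 0.00634). STMN2 rose 9.15-fold and STMN4, a stathmin of neurons, at least 1.95-fold, while GAP43 was lower again (log2 -1.27). SNAP25 was again counted as higher (log2 1.79), with its other probe at -0.14. Here too the arrays stood apart, with list means of 8.77 and 8.64 on arrays 1 and 2 and 9.38 and 9.35 on arrays 3 and 4, and with STMN4 at 7.55, 7.41, 8.68 and 8.58.

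Pluripotency genes were lower in 6 of 26 cases, higher in 2 and did not pass in 18 (median -0.64, adjusted p = 0.000708, and adjusted p = 0.0299 with an estimated correlation). DPPA2 fell by 2.37 and was still detected on 1 of 4 arrays. TERF1, a telomere binding protein, and TRIM71, a regulator of early embryonic transcripts, both named after their values were seen, fell by 1.45 and 1.22 (-0.90 by the other TRIM71 probe), and NODAL remained at least 4.19-fold above ESCs. FGF and ERK feedback genes were lower in 5 of 16 cases and higher in 2 (median -0.36, adjusted p = 0.0475, but adjusted p = 0.0865 with an estimated correlation and 0.0546 with the replicate block). EGR1 and FGFR1, an FGF receptor (3.13-fold), fell. DUSP4 and DUSP6, phosphatases that limit ERK, rose (log2 1.28 and 1.27), DUSP4 and DUSP6 being named after their values were seen. Without any 1 of 10 arrays, 1-week array 4 and 2-week array 1 excepted, the adjusted p of this list lay between 0.05 and 0.09. In the list of immediate early and unfolded protein response genes 8 of 20 were lower, among them FOS (median -0.52, adjusted p = 0.000438, but adjusted p = 0.081 with an estimated correlation).

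Further lists passed camera at 2 weeks only with the preset correlation. BMP targets were higher in 6 of 12 cases and lower in 1 (median 0.85, or 1.21 with bounds, adjusted p = 0.0176, but adjusted p = 0.0584 with an estimated correlation). The lower member was ID1, an inhibitor of bHLH factors (log2 -1.23), named after its value was seen. MSX1 rose 22.7-fold. For WNT targets 7 of 10 were higher and 1 was lower, WIF1, a secreted WNT inhibitor (log2 -1.35), likewise named after its value was seen (median 2.09, or 1.20 with bounds, adjusted p = 0.0083, but adjusted p = 0.226 with an estimated correlation). DKK1, another inhibitor of WNT signalling detected on 3 of 4 ESC arrays, rose 12.1-fold. WNT target means at 2 weeks were 9.81, 9.84, 9.52 and 9.56 on arrays 1 to 4, and trophoblast means 8.60, 8.57, 8.86 and 8.89. Endothelial genes were higher in 6 of 11 cases and lower in 1, the lymphatic receptor FLT4 (log2 -1.26), chosen after its value was seen (median 1.03, or 0.36 with bounds, adjusted p = 0.00771, but adjusted p = 0.0584 with an estimated correlation). VWF, von Willebrand factor, detected on 2 of 4 ESC arrays, rose 8.57-fold and CDH5 at least 1.71-fold. Neural crest genes were higher in 4 of 11 cases and lower in 1 (median 0.84, or 0.26 with bounds, adjusted p = 0.0395, but adjusted p = 0.128 with an estimated correlation, and 0.0532 to 0.107 without ESC array 1 or any 1 of the 2-week arrays). Without any 1 of the 2-week arrays the neural crest median was 0.51 to 0.52. Trophoblast genes were higher in 4 of 8 cases (median 0.98, or 0.28 with bounds, adjusted p = 0.0434, but adjusted p = 0.153 with an estimated correlation, and 0.05 to 0.0649 without ESC array 1 or 2 or 2-week array 3 or 4). SLC40A1 rose at least 17.1-fold and TFAP2A 5.28-fold, with other TFAP2A probes at -0.56 to 2.54. Simple epithelium had 5 of 14 members lower and 2 higher, the keratin genes KRT8 (log2 1.20) and KRT18 (log2 1.04), both named after their values were seen (median -0.68, adjusted p = 0.023, but adjusted p = 0.0626 with an estimated correlation). The KRT18 call again rested on the choice of probe, with its other probes at -0.71 to -0.19. ELF3, an epithelial ETS factor, fell 3.08-fold.

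Lists that did not pass camera at 2 weeks again held single called genes, and p-values of lists here are from camera. By fry, mitosis (adjusted p = 0.000102), hypoxia (0.000124) and DNA replication genes (0.0273) passed downward. Ribosomal protein (0.00208), smooth muscle (0.0273) and p53 target genes (0.0238) passed upward by fry. Erythroid genes had 3 of 7 members higher and 1 lower, the hemoglobin chaperone AHSP (log2 -1.25), named after its value was seen (median -0.13, mean 0.57, test downward, adjusted p = 0.952). HBG2 exceeded ESCs at least 1.49-fold, at 8.34 and 8.29 on arrays 1 and 2 and 6.99 and 7.04 on arrays 3 and 4, where the list means were 7.69, 7.68, 7.08 and 6.99. Of 5 leukocyte genes LCP1 was at least 4.89-fold higher and CORO1A lower (log2 -1.19, list median -0.54, adjusted p = 0.349). ACTA2 rose 6.03-fold among 8 smooth muscle genes (list median -0.15, mean 0.23, test downward, adjusted p = 0.951). DSC3, of 4 surface ectoderm genes, was at least 7.25-fold higher. NDRG1 rose 9.41-fold in the hypoxia list, where 1 of 23 was higher and 3 were lower (median -0.17, adjusted p = 0.302). SC5D, a late enzyme of cholesterol synthesis, rose 2.30-fold (list of 16, median -0.22, adjusted p = 0.375). TP53INP1, a stress protein induced by p53, rose 2.72-fold, with 2 of 14 p53 targets higher (median -0.12, mean 0.02, test downward, adjusted p = 0.951). RRM2, a subunit of ribonucleotide reductase, was the called member of 27 DNA replication genes (log2 1.04, adjusted p = 0.011, list median -0.16, adjusted p = 0.381). Its ESC arrays read 9.31, 9.29, 7.68 and 7.76, its difference was 0.77 without ESC array 3, 0.79 without ESC array 4 and 0.99 without 2-week array 2, and it did not pass with pair means (adjusted p = 0.0959). Mitosis genes (median -0.10, adjusted p = 0.381) and ribosomal protein genes (median 0.07, or -0.17 with median scaling, adjusted p = 0.419) did not pass.

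At 2 weeks 873 genes were higher and 636 lower than in ESCs, 14.3% of those tested, and 57.9% of the called genes were higher. The groups did not overlap for any of the 1509 called genes and for 55.5% of all tested genes. The 2.86% given by chance again takes the arrays as exchangeable, which the array pairs put in doubt. Bounds stand for 431 of the higher and 145 of the lower genes. Adjusted over the list alone, all 28 lists kept their counts.

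**Figure D2:**
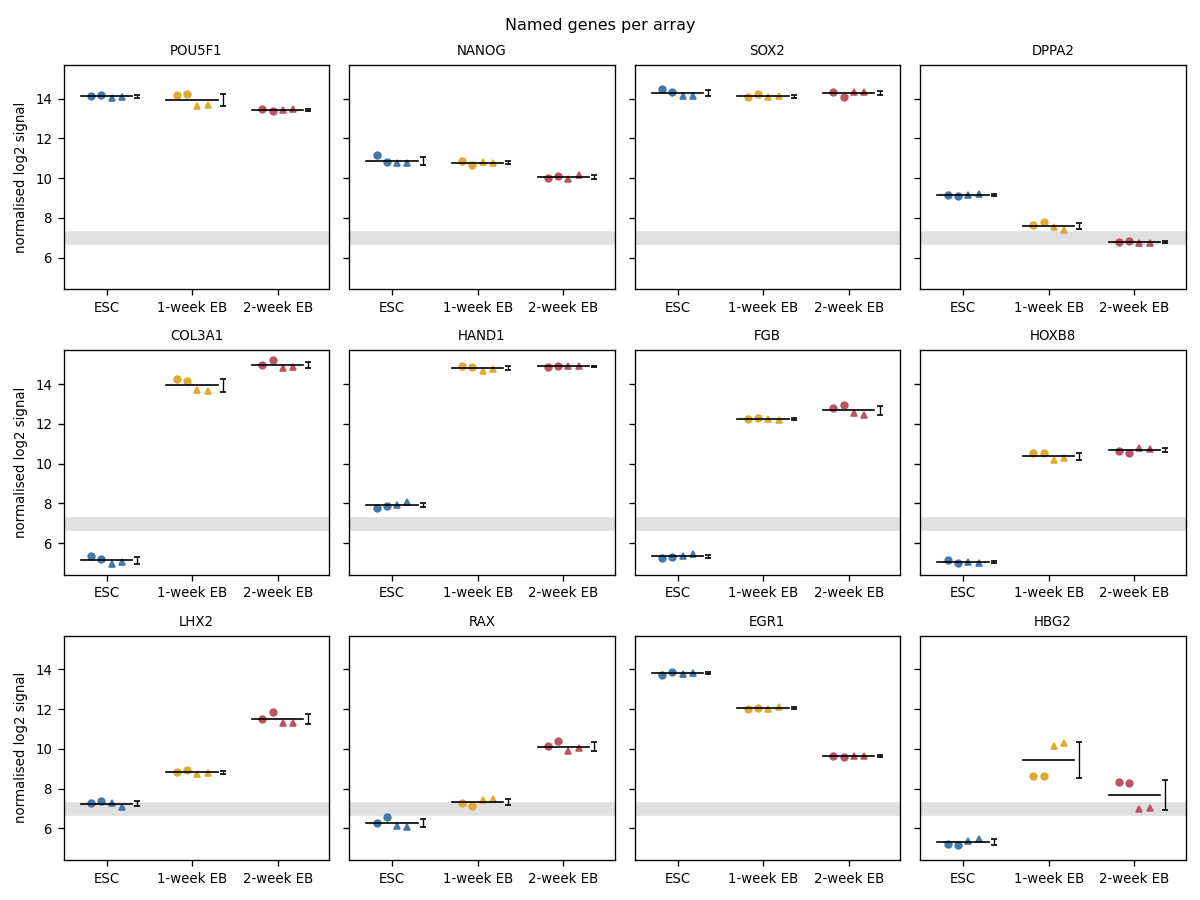
Normalized log2 level of 12 named genes on each of the 12 arrays (vertical axis, log2 units), by group on the horizontal axis. Circles are arrays 1 and 2, triangles arrays 3 and 4, black lines group means with the SD of 4 arrays, and the grey band is the range of the lowest detected level, 6.67 to 7.28. COL3A1, FGB and HOXB8 lie below that band in ESCs and above it in EBs, while POU5F1 stays between 13.44 and 14.11 in the group means.

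The comparison of 2-week with 1-week EBs asked what continued to change in the second week. The rises named by the rule were RAX, LHX2, SIX3 and FEZF1. RAX, a homeobox factor of the eye field, rose 6.91-fold, from 7.33 ± 0.17 to 10.12 ± 0.22 (SD, n = 4, adjusted p = 1.31e-08), LHX2 6.40-fold, SIX3, a forebrain and eye homeobox factor detected on 2 of 4 1-week arrays, 5.57-fold, and FEZF1, a forebrain zinc finger factor, at least 3.26-fold. The falls named were those of EGR1 at 5.33-fold (log2 -2.41, SE 0.06), ANKRD37, a hypoxia-responsive gene, at 4.66-fold, ZNF296, a zinc finger gene of pluripotent cells, at 4.01-fold and CCN1, a matricellular protein, at 3.93-fold.

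Of 18 neural progenitor genes 6 were higher and 12 did not pass (median 0.61, adjusted p = 2.88e-09, but adjusted p = 0.0717 with an estimated correlation). Neuron genes were higher in 4 of 23 cases (median 0.45, adjusted p = 0.00122, but adjusted p = 0.47 with an estimated correlation). STMN4 rose 2.95-fold and STMN2 2.68-fold, with STMN4 detected on 2 of 4 1-week arrays and not passing with pair means (adjusted p = 0.0736). Mesenchyme and matrix genes were higher in 3 of 23 cases (median 0.56, adjusted p = 6.44e-10, but adjusted p = 0.104 with an estimated correlation). MGP, an inhibitor of calcification, rose 4.40-fold and DCN 2.80-fold. Endothelial genes had 1 of 11 members higher, VWF at 2.96-fold (median 0.33, adjusted p = 0.000771, and adjusted p = 0.0314 with an estimated correlation, but 0.0527 in the series matrix). Imprinted genes were higher in 3 of 13 cases (median 0.53, adjusted p = 0.000336, and adjusted p = 0.021 with an estimated correlation), and DLK1, a Notch-related growth regulator, rose 4.83-fold.

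Several lists shifted as a whole while their members stayed under the 2-fold minimum. Pluripotency genes had a median of -0.34 (adjusted p = 4.96e-06, and adjusted p = 0.00902 with an estimated correlation), with DPPA2 at -0.81, POU5F1 at -0.50 (adjusted p = 0.0081), NANOG at -0.73 (adjusted p = 0.000118) and SOX2 at 0.15 (adjusted p = 0.234). Liver and yolk sac genes had a median of 0.17 (adjusted p = 0.0051, but adjusted p = 0.12 with an estimated correlation and 0.175 in the series matrix). ALB, serum albumin, differed by 0.98 without being called, its 2-week arrays reading 9.66 and 9.56 against 8.43 and 8.48, and by 1.18 and 1.17 without arrays 3 and 4 of them in turn. Endoderm genes had a median of 0.21 (adjusted p = 0.0405, but adjusted p = 0.224 with an estimated correlation, 0.0511 in the series matrix, and 0.0616 to 0.108 without 1-week array 1 or 2 or 2-week array 1, 3 or 4), with KRT19, a keratin of simple epithelia, at 0.44. Cardiomyocyte genes had a median of 0.21 (adjusted p = 0.0411, but adjusted p = 0.275 with an estimated correlation, 0.226 in the series matrix and 0.0633 with the replicate block). Without 1-week array 2 or 4 or 2-week array 1, 3 or 4 that adjusted p was 0.0568 to 0.19. HAND2, a partner of HAND1 in heart, differed by 0.99, and by 1.02 to 1.07 without 1-week array 1 or 2 or 2-week array 2 or 4. Simple epithelium (median -0.32, adjusted p = 0.00122) and mitosis (median -0.18, adjusted p = 0.00828) shifted downward and held with an estimated correlation (adjusted p = 0.03 and adjusted p = 0.0431). In the series matrix the simple epithelium list did not pass (median -0.22, adjusted p = 0.0707).

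FGF and ERK feedback genes had a median of -0.36 with 1 of 16 members, EGR1, lower (adjusted p = 4.01e-05, and adjusted p = 0.0121 with an estimated correlation), and of 20 immediate early and unfolded protein response genes 3 were lower, FOS by 3.44-fold (median -0.54, adjusted p = 0.000237, but adjusted p = 0.0924 with an estimated correlation). Erythroid genes were lower in 3 of 7 cases over all genes tested and in 4 adjusted over the list alone (median -1.05, or -1.27 with bounds, adjusted p = 0.0369, but adjusted p = 0.224 with an estimated correlation and 0.0666 with the replicate block). HBG2 fell 3.42-fold (adjusted p = 0.0052), but by 0.35 on the log2 scale in arrays 1 and 2, where it lay at 8.66 and 8.66 at 1 week and 8.34 and 8.29 at 2 weeks, and pair means gave an adjusted p of 0.125. Without 1-week array 3 or 4 or 2-week array 4 the erythroid list had an adjusted p of 0.0565, 0.0528 and 0.0535.

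Other lists did not pass camera in the second week, and p-values of lists here are from camera. By fry, BMP targets (adjusted p = 0.003616), p53 targets (0.002322) and ribosomal proteins (0.009717) passed upward and DNA replication (0.04606) passed downward. FGF8, a signal of the primitive streak and of brain organizers, rose at least 1.67-fold, the called member of 10 mesendoderm genes (median 0.13, adjusted p = 0.291), HOXD1 fell at least 1.16-fold among 13 HOX genes (median 0.11, adjusted p = 0.404), and LMX1A, a LIM homeobox factor of roof plate and midbrain, rose at least 1.44-fold among 11 neural crest genes (median 0.14, or -0.02 with median scaling, adjusted p = 0.552). In the series matrix FGF8, HOXD1 and LMX1A differed by 0.78, -0.70 and 0.79 and were not called. DSC3 rose 2.05-fold, with log2 differences of 0.97 to 0.98 without 1-week array 3 or 4 or 2-week array 1. Of 12 BMP targets GREM1, a secreted BMP inhibitor detected on 3 of 4 1-week arrays, rose 3.11-fold and NOG, another such inhibitor named after its value was seen, fell (log2 -1.10, list median 0.20, adjusted p = 0.339). The hypoxia list had 1 of 23 members higher and 2 lower, ANKRD37 among them (median -0.05, test upward, adjusted p = 0.692). Trophoblast genes (median -0.12, or 0.13 in the series matrix, adjusted p = 0.579, KRT7, a keratin, at -0.63), WNT targets (0.17, adjusted p = 0.552), leukocyte genes (0.02, mean -0.01, adjusted p = 0.972), smooth muscle genes (0.02, mean -0.04, test downward, adjusted p = 0.775), DNA replication (-0.12, adjusted p = 0.241), ribosomal proteins (0.06, or 0.00 with median scaling, adjusted p = 0.291), cholesterol synthesis (-0.05, adjusted p = 0.847) and p53 targets (0.01, or -0.11 with median scaling, adjusted p = 0.552) did not pass.

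In the second week 93 genes were higher and 53 lower, 1.38% of those tested, and 63.7% of the called genes were higher. With median scaling, which put the median of all genes at -0.12, 69 were higher and 84 lower, so that 45.1% were higher. The groups did not overlap for 145 of the 146 called genes and for 31.9% of all tested genes. Beside this, the 2.86% given by chance holds only for exchangeable arrays and would be larger with the array pairs as units. Bounds stand for 20 of the higher and 17 of the lower genes. Except for the erythroid list, counts adjusted over the list alone were the same.

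Calls against ESCs overlapped between both EB stages. Of 967 genes called at 1 week and 1509 at 2 weeks, 610 genes were higher and 285 lower at both stages, and 0 went in opposite directions by limma, where independent lists of these sizes would share 53.1 and 19.5, and 65.5 in opposite directions, and 100 simulations of unchanged groups that share the ESC arrays gave 0. Unchanged genes are hardly ever called, so the simulated 0 was fixed in advance. With the ESC arrays split between the comparisons, 588 and 256, or 602 and 260, genes were shared, and 0 or 1 went in opposite directions. The differences correlated across genes at 0.943 (simulated 0.5), with a covariance of 0.641 (simulated 0.00659). SST, the peptide hormone somatostatin, MGP and DLK1 rose in both weeks: SST at least 7.37-fold and then 4.04-fold, MGP at least 6.14-fold and then 4.40-fold, and DLK1 4.37-fold and then 4.83-fold. FOS fell 4.62-fold and then 3.44-fold, EGR1 3.37-fold and 5.33-fold, and CCN1 2.90-fold and 3.93-fold. Such genes, called the same way in both weeks, numbered 53, of which 45 rose and 8 fell, against 7.29 for independent lists and 0 in the simulations, and 79 or 61 with the 1-week arrays split between the steps. The simulated 0 was again fixed in advance.

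In 13 genes the change of the first week turned back in the second, 8 after a rise and 5 after a fall, against 6.08 for independent lists, 0 in the simulations, which was fixed in advance, and 14 or 13 with the 1-week arrays split. When the array pairs were regrouped as wholes, 7 of 45 groupings, the real one included, gave as many such genes, so chance is not excluded, although the 6 others also carry real differences between the groups. HBG2 and HBG1, fetal globin genes whose near-identical sequences leave their separate levels uncertain, rose at least 5.10-fold and 4.23-fold and then fell 3.42-fold and 3.18-fold, HBG1 being detected on 3 of 4 2-week arrays. Like HBG2, HBG1 followed the array pairs, at 8.35, 8.35, 10.03 and 9.94 at 1 week and 8.19, 7.91, 7.06 and 6.85 at 2 weeks. Its difference in the second week was -0.31 in arrays 1 and 2 and did not pass with pair means (adjusted p = 0.132). ANKRD1, a mechanosensitive gene of striated muscle, rose at least 1.65-fold and fell at least 1.84-fold. UPK1A, a uroplakin of urothelium, fell 4.59-fold and rose 2.54-fold, GARIN1B fell at least 5.41-fold and rose at least 1.69-fold, and GNG8, a G protein gamma subunit, fell at least 1.77-fold and rose at least 1.80-fold. In the series matrix HBG1 (adjusted p = 0.105), ANKRD1, GNG8 and GARIN1B were not called in the second week. The changes of both weeks correlated across genes at 0.342 (simulated -0.5), with a covariance of 0.0826 (simulated -0.00659).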

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

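The splits of the arrays were planned. The limits for the test of labelling between arrays of a group were set before that test was run, but its gene families were chosen after their values were seen. The tests of array pairs, the splits that keep array pairs together and the tests of persisting pluripotency transcripts and of cells in S phase were chosen only after the result was seen. The groups, gene lists, named-gene rule, tests and most alternatives were set before the data were examined.

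Other splits of the arrays were set beside the real groups. For 1-week EBs against ESCs, 1 of the 35 splits of the 8 arrays, the real one, called as many as 967 genes (highest other 3) and passed as many as 15 lists (highest other 11). The other splits mix both groups, so the real difference widens their spread and few gene calls are expected from them. Chance could be excluded only if the arrays were exchangeable, which the array pairs put in doubt. Among the 7 other splits that part as many number pairs as the real one, the highest counts were 3 genes and 11 lists. For 2-week EBs against ESCs it was again 1 of 35 for 1509 genes (highest other 0 by limma) and for 17 lists (highest other 16), and for 2-week against 1-week EBs 1 of 35 for 146 genes (highest other 3) and for 14 lists (highest other 13). Because the list counts of other splits came close to the real ones, the number of passing lists says less than the number of genes. A split that set arrays 1 and 2 of both groups against arrays 3 and 4 passed 0, 1 and 6 lists by camera in the 3 comparisons. Of 100 drawn splits of all 12 arrays into 3 groups, the real one included, 2 gave as many as 13 genes called in both steps in opposite directions and 1 gave as many as 53 in the same direction (highest other 0), so chance could be excluded for both if the arrays were exchangeable. The array pairs (consensus correlation 0.544) put that in doubt for every split above. When the 6 pairs were kept together, 7 of 45 splits, the real one included, gave as many as 13 opposite calls (highest other 1055), so chance is not excluded for these, and 1, the real one, gave as many as 53 in the same direction (highest other 3). For 2 groups only 3 such splits exist, too few for a test; the other 2 called at most 3 genes. With pair means the counts were 11 and 46, and the 13 opposite calls include HBG2 and HBG1, which followed the pairs and were not called between both weeks with pair means (HBG2, 2-week against 1-week EBs, adjusted p = 0.125; HBG1, 2-week against 1-week EBs, adjusted p = 0.132). Under other alternatives the opposite count went both ways, to 2 to 5 in several and to 0 with treat of limma, but to 22 with arrays 1 and 2 alone, 17 with arrays 3 and 4 alone and 464 with no fold minimum. Among the 100 drawn splits the highest other count of opposite calls, 232, came from one that kept the 2-week arrays together between mixed groups of 2 ESC and 2 1-week arrays each, which points to a structure of the samples, the distance between the real groups. The 6 other splits of whole pairs with 13 or more likewise set all ESC or all 2-week arrays between 2 other groups, so they too carry real differences and are no measure of chance alone.

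Arrays 1 and 2 and arrays 3 and 4 of a group resembled each other in ESCs and 1-week EBs, and in EBs the mean levels of several lists stood apart between these pairs, at 1 week by 0.86 for erythroid, 0.36 for neural progenitor, 0.31 for neuron and -0.31 for mesenchyme genes and at 2 weeks by 0.66 for neuron, -0.65 for erythroid, -0.33 for mesendoderm, 0.29 for trophoblast and -0.29 for WNT target genes. The pair difference correlated at 0.242 between ESCs and 1-week EBs, the groups in which both pairs were seen. That argues against a shared batch difference as the whole cause there, while a shared part stays open. With 2-week EBs it correlated at 0.0339 for ESCs and 0.00276 for 1-week EBs. Arrays 1 and 2 of the 2-week group did not pair, so these 2 values decide nothing. A different cell make-up of the pairs was tested with the detected members of the lineage lists, without the neural lists that had prompted the test, against 10000 random lists of detected genes matched for level. The mesenchyme, mesendoderm and trophoblast lists, already seen to stand apart between pairs, stayed in that set. The percentiles are therefore not free of values seen before. The median pair difference lay at percentile 100 in 1-week EBs (0.21 against 0.12, 99 genes) and 2-week EBs (0.19 against 0.11, 97 genes), and at 22.7, 100 and 100 in the 3 groups in an earlier form with all 148 lineage genes, replaced because it took in neural and undetected genes. For EBs a different make-up remains a candidate explanation found and tested on the same data, while in ESCs, where 138 genes differed at least 2-fold between pairs, the 42 detected members lay at percentile 52.6, which decides nothing.

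Pluripotency transcripts such as POU5F1 and SOX2 stayed high in EBs. A remaining share of undifferentiated cells as the only source would lower all of them by about the same true factor. The 2-week differences of the 24 list members not called higher had an SD of 0.71, from -2.37 to 0.90. Their median SE of 0.09 covers only the spread between arrays. Compression of bright probes and the offset on dim ones can also make measured differences unequal, and 11 list members lay at log2 13 or above in ESCs. The unequal differences therefore do not decide against such a share. Some bright probes were able to fall: 3.17% of the 694 genes with an ESC level of log2 13 or above were lower at 2 weeks. Of the 9868 other genes 6.22% were lower, against which the share of bright genes was set. The share of bright genes is smaller, so some compression of bright probes remains possible, also for POU5F1 and SOX2. Undifferentiated cells, alone or together with other cell types that express some of these genes, stay open, as no measure of single cells was available.

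Small nucleolar RNA and histone transcripts were lower in EBs, with medians of -1.34 and -1.01 at 1 week, where 26 of 37 and 16 of 31 genes were called lower (adjusted p = 0.0998 and 0.00734 with an estimated correlation). By the rule set, fewer cells in S phase would have lowered the DNA replication list, but its median was -0.0498 (SE 0.04) at 1 week. That list mean also differed by -0.18 between the array pairs of ESCs. Its transcripts do not count cells in S phase, so the share of such cells is not settled. Labelling or RNA handling that varies between arrays of a group was left undecided: the largest of 6 differences between pairs was -0.35, for small nucleolar RNAs at 1 week, below the size set for it as a cause and above the size set against it. Handling that differed between the groups cannot be told apart from a change in the cells, since each group was a separate set of RNA samples and these transcripts mostly lack the poly(A) tail that common labelling methods use.

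Single arrays that stood apart from the other 3 of their group numbered 18 in 321 group tests, where chance gives about 1 in 20, or 16.1. The correlation between signal and series matrix was 0.938 on 2-week array 2; 0.999 was the highest of that group. In the matrix this array lay below its own signal by more than log2 2 at 937 of 15904 probes and at none of them above it by as much. Mean levels of lists that stood apart were pluripotency 11.33 and endothelium 7.75 on 1-week array 2, neural crest 8.77, smooth muscle 11.46 and immediate early genes 10.08 on 2-week array 1, and simple epithelium 10.22 on 2-week array 4. Among genes, ESC arrays stood apart for FOXA2 (5.49, array 2), NANOG (11.18, array 1), KRT7 (7.82, array 4) and GNG8 (7.48, array 1). In 1-week EBs these were TTR (11.57), TP53INP1 (9.27) and ZNF296 (11.54), all on array 1. In 2-week EBs they were MSX1 (11.81) and SOX2 (14.11) on array 2, SC5D (11.57) on array 4 and FEZF1 (8.77) on array 1.

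By camera between both EB stages with the preset correlation, 14 lists differed in their distance from ESCs, of which 6 passed with an estimated correlation too: pluripotency, endothelium, FGF and ERK feedback, simple epithelium, imprinted and mitosis genes. The other 8 did not pass with it (adjusted p = 0.0717 for neural progenitor, 0.104 for mesenchyme and matrix, 0.47 for neuron, 0.224 for endoderm and for erythroid, 0.275 for cardiomyocyte, 0.12 for liver and yolk sac and 0.0924 for immediate early genes). Medians of the difference were 0.61 for neural progenitor, 0.56 for mesenchyme and matrix, 0.53 for imprinted, 0.45 for neuron, 0.33 for endothelium, 0.21 for endoderm, 0.21 for cardiomyocyte and 0.17 for liver and yolk sac genes. They were -1.05 for erythroid, -0.54 for immediate early, -0.36 for FGF and ERK feedback, -0.34 for pluripotency, -0.32 for simple epithelium and -0.18 for mitosis genes. Of 2335 kept probes without a gene name here, 214 were called at 1 week (79 higher, 135 lower), 350 at 2 weeks (117 higher, 233 lower) and 24 between both weeks (15 higher, 9 lower).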

How the results depend on the processing

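Chosen only after the data were seen were the tests with pair means, the pair block, arrays 1 and 2 alone, arrays 3 and 4 alone, and the series matrix without 2-week array 2. Of 4320 values of named genes under alternatives, 4209 kept direction and call, 72 lost the call, 24 gained one and 15, none of them called, changed direction. Of 1377 list values, 1277 kept direction and call, 83 lost it, 15 gained one and 2 changed direction, and 28 more list directions turned with neither test passing. In the order lower at 1 week, lower at 2 weeks, higher and lower between weeks, genes called in both steps in opposite directions and in the same direction, counts were 174, 382, 57, 17, 3 and 33 without background correction, which compresses dim probes by construction. With normexp and an offset of 50 all but the last were 190, 415, 60, 19 and 5, the larger offset compressing dim probes too. The series matrix gave 183 lower at 1 week, 55 and 27 between weeks, and 4 and 27 for the steps, and without 2-week array 2 it gave 185, 391, 61, 18, 4 and 33. Median scaling gave 84 lower between weeks. For the matrix and median scaling the cause was not tested. Detection on all 12 arrays, which tests fewer genes, gave 219 higher and 161 lower at 1 week, 379 and 357 at 2 weeks, 33 and 20 between weeks, and 2 and 16 for the steps. With no fold minimum the group counts were 2866, 2620, 3240, 3355, 1306 and 1492, with 464 genes called in both steps in opposite directions and 1396 genes called in both steps in the same direction. Treat, a stricter test, gave 128 and 301 lower at 1 and 2 weeks, 15 and 9 between weeks, and 0 and 8 for the steps. Arrays 1 and 2 alone gave 82 lower between weeks and 22 opposite steps, where arrays 3 and 4 alone gave 51 and 17, and the cause was not tested. Of 46 passing list tests 18 passed with an estimated correlation. Without 1 array in turn, counts ranged from 621 to 660 and 246 to 336 at 1 week, 827 to 895 and 529 to 656 at 2 weeks, 76 to 101 and 46 to 58 between weeks, and 9 to 15 and 51 to 60 for the steps. The replicate block gave 643 and 324 at 1 week and called the same numbers elsewhere, and it lost the lists of FGF and ERK feedback at 2 weeks (adjusted p = 0.0546), cardiomyocyte (0.0633) and erythroid genes (0.0666) between weeks and changed no other call. Same-numbered arrays deviated together at -0.0426 to 0.0636 for 2-week EBs and ESCs and at -0.0856 to 0.135 for both EB stages, so the numbers pair arrays in neither. Differences that changed direction were POU5F1 at 1 week (0.0523 with only arrays 1 and 2), NANOG at 1 week (0.0427 with median scaling, 0.0231 with only arrays 3 and 4, -0.14 to 0.00332 without 1 array, the highest without ESC array 1) and that of SOX2, 2-week EBs against ESCs (0.0361 as the mean of probes, 0.0740 with the most variable probe, 0.14 with array weights, 0.19 with only arrays 3 and 4, -0.0500 to 0.0673 without 1 array, above 0 without ESC array 1 or 2 or 2-week array 2). GNG8 at 2 weeks was -0.29 in the series matrix, -0.0197 with only arrays 3 and 4 and -0.0710 to 0.12 without 1 array (below 0 without ESC array 1 or 2-week array 1), and the cause was not tested for these genes. With fry the lists of smooth muscle (median -0.15, adjusted p = 0.0273) and p53 targets (median -0.12, adjusted p = 0.0238) passed upward at 2 weeks, where camera pointed downward. Fry also passed 15 list results that camera did not, among them FGF and ERK feedback at 1 week (adjusted p = 2.6e-06). It lost 1, the neuron list between weeks (adjusted p = 0.06325). A chip block was not run, as the column names did not identify chips. Signal over background limits folds of genes undetected in a group to bounds and leaves changes below log2 6.67 to 7.28 unmeasured.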

Other observations

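The families, values and tests of this part were all chosen only after the result was seen. Of 10 gene families tested with camera, adjusted over the 30 tests, small nucleolar RNAs, which guide the modification of ribosomal RNA, were lower in EBs in 26 of 37 cases at 1 week and 29 at 2 weeks (medians -1.34 and -1.62, adjusted p = 2.43e-14 and 5.17e-13, but adjusted p = 0.0998 and 0.0998 with an estimated correlation), and all 37 had negative differences at both stages. Histone genes were lower in 16 of 31 cases at 1 week and 19 at 2 weeks (medians -1.01 and -1.19, adjusted p = 2.46e-14 and 9.33e-11, and adjusted p = 0.00734 and 0.0084 with an estimated correlation), with H2BC12, a histone H2B gene, higher at 2 weeks (log2 1.11). Both families kept their direction with median scaling and in the series matrix. Metallothioneins, which bind zinc and copper, went both ways. MT1G and MT1H fell by 2.67 and 2.71 at 1 week, while MT2A rose by 1.06 at 1 week and 2.12 at 2 weeks. As a family they had medians of -1.10 and -0.94 (adjusted p = 0.00861 and 0.194, and adjusted p = 0.283 and 0.535 with an estimated correlation).

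Collagen genes were higher in 13 of 30 cases at 1 week and 20 at 2 weeks (medians 0.91 and 1.37, adjusted p = 6.57e-07 and 1.97e-08, but adjusted p = 0.141 and 0.117 with an estimated correlation). COL15A1, a basement membrane collagen, stood at 3.57 and 5.35. Apolipoprotein genes were higher in 5 of 8 cases at both stages (medians 3.90 and 4.17, adjusted p = 7.1e-06 and 5.95e-05, and adjusted p = 0.0084 and 0.0101 with an estimated correlation). Keratin genes were higher in 4 of 8 cases at both stages (medians 0.83 and 0.59, adjusted p = 0.00861 and 0.0262, but adjusted p = 0.0998 and 0.117 with an estimated correlation). These counts include KRT18, whose other probes lay at -0.47 to 0.15 and -0.71 to -0.19. Between both weeks, 6 of 8 genes of the eye field and anterior forebrain rose (median 2.37, adjusted p = 3.71e-11, and adjusted p = 0.0101 with an estimated correlation), among them PAX6, an eye master regulator (log2 2.27), and HESX1, a forebrain and pituitary factor (log2 1.31). That set was assembled around the leading genes of the same comparison, so its p is not independent evidence. Claudins (adjusted p = 0.173 and 0.102), heat shock proteins (0.322 and 0.673) and zinc finger genes (0.346 and 0.178) did not pass at 1 or 2 weeks.

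The share of the 2-week change present at 1 week had been compared between 22 neural and 34 mesendoderm, endoderm and liver genes called higher at 2 weeks, by a permutation test (p = 1e-05). It is not used, because 14 and 29 of these genes were undetected in ESCs, so that their changes are only bounds, and because the sets were picked from the same values. No order of rise is given.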
